A study of Triticum aestivum with 48 samples.

How the data were processed

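Total RNA of whole wheat leaves (Triticum aestivum) was measured on 48 Affymetrix wheat arrays with biotin-labelled target. The leaves came from seedlings at the second-leaf stage of paired near-isogenic lines, called the Yr5 isoline and the yr5 isoline in the labels. Yr5 is a resistance gene against the stripe rust fungus Puccinia striiformis f. sp. tritici. Seedlings were inoculated with the fungus or mock-inoculated and harvested 6, 12, 24 or 48 h later, which gives 16 groups of 3 arrays. The series' own design line repeats 24 h and omits 48 h, while the label of each array gives 48 h for the last harvest; the array labels were used. Per the labels' growth protocol, the 3 replicates of a group are biological replications, each genotype was planted in its own flats, and rows of seedlings were assigned at random to harvest times.

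The deposited value of each of the 61290 probe sets on each array is a MAS5 signal intensity on a linear scale; MAS5 is the tool named in the labels, and its version and scaling target are not given in the sources used here. On every array the mean signal after trimming 2% of probe sets at each end was 500.3, so the deposited arrays had been scaled to a common mean. Array medians ran from 88.6 to 121.2 signal units, or 6.71 to 7.10 on the log2 scale used here. This range is within the 0.5 set as the limit for leaving arrays unscaled, and no further rescaling was done. The table held 0 columns of other samples. For arrays, the number of arrays limits the precision.

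Signals were analysed as log2(signal + 16). The 111 control probe sets were left out of the tests, and a probe set was tested where it exceeded its array's median in at least 3 of the 48 arrays. This left 46352 probe sets tested and 14827 not tested. A mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation that follows the trend of variance with mean signal, and all 48 arrays shared 1 estimate of the spread. A probe set is called when its two-sided p, adjusted by Benjamini and Hochberg within the comparison, is under 0.05. The p-values measure spread between biological replicates within a group. Comparisons that combine or contrast times take arrays of the same replicate number at different times as independent. Whether they are was not tested, so their p-values and counts of same-numbered pairs may overstate the evidence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

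The planned comparisons were inoculated against mock leaves in each isoline at each time, the difference of these responses between the isolines at each time, the mean response of each isoline over the 4 times, the difference between the isolines in mock leaves, and time in mock leaves (a moderated F test over 12, 24 and 48 h against 6 h). These tests, the filter, the log offset, the gene lists, the rule for named genes and the alternatives were written before the data were examined, except where the text says that a choice came after. Chosen after the data were seen were the contrast of 48 h with 24 h in mock leaves, the response at 24 h against other times, the isoline difference in inoculated leaves, the mean difference and mean of both isolines' responses, and the replicate number as a block within each time.

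Gene symbols came only from the table that pairs this array's probe sets with genes. It gives exactly 1 symbol to 1273 probe sets, covering 771 genes; 770 of these genes were found in the RefSeq gene table of assembly IWGSC CS RefSeq v2.1, used here for names and synonyms alone. Among tested probe sets, 1090 had a symbol (2.35%), for 703 genes, and 45262 had none; 88 of the tested genes have a symbol or synonym other than a LOC number. COMT1 is the synonym of LOC543449. Where a gene has only a LOC symbol, no function is stated. The rule for named genes took, per comparison, up to 12 called genes with the largest rise and 6 with the largest fall whose inoculated arrays all lay on 1 side of the mock arrays, up to 4 called members of each fixed list, and up to 2 unannotated probe sets per direction, whose identifiers are not printed here. The rule did not cover the time course of mock leaves, so genes outside the lists were chosen there after their values were seen, as were PR5, PEAMT1 and SAHH in the responses.

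Of 25 fixed gene lists, 15 had at least 1 tested gene and 10 had none. The lists with none were WRKY, NAC with MYB and ERF, receptor kinases, jasmonate with ethylene, cytochrome P450 with glycosyltransferases, transporters, heat shock, secretion, circadian clock, and fungal or other-organism sequence. The lists with tested genes were PR proteins, phenylpropanoid and lignin, peroxidases, glutathione and antioxidant, salicylate, tryptophan and shikimate, photosynthesis, ribosome, cold with dehydration and LEA, sucrose with starch and fructan, dividing cells, leaf epidermis, vascular tissue, stomata, and housekeeping. A gene with several probe sets was represented in its list by the probe set with the highest mean. Only the list of dividing cells reached the 5 genes needed for camera, limma's competitive set test, which was run with a preset correlation of 0.01 on 12 comparisons.

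Arrays of the same replicate number were checked for shared deviation. Within each isoline and time, the deviations of the inoculated and the mock array with the same number from their group means correlated across probe sets by 0.04 to 0.29 (median 0.13). The correlation was above 0 in 24 of 24 pairs and above 0.1 in 18 of 24, and 23 of 24 inoculated arrays correlated best with the mock array of their own number. The set criterion, above 0.1 in every pair, was therefore not met. No label states that the number marks a batch or a shared planting; the growth protocol says only that genotypes were planted in their own flats for each biological replication. The number was treated as a possible batch in the blocked fits because hybridisation spike-ins were highest in replicate 3 in 15 of the 16 groups. Calls of the blocked fits had been seen when this was settled, and the block within each time was itself chosen after seeing the data. The fit without a block, fixed earlier, gives every count and adjusted p in the text unless a block is named.

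Alternatives changed 1 choice at a time: an offset of 64, quantile normalization, centring of array medians, no filter, a filter at the 75th percentile, no variance trend, array weights, only the arrays compared, the replicate number as a block over all arrays or within each time, and leaving out each array in turn (each replicate number in turn for means over times, for time in mock leaves and for the list tests). The procedure was tested on simulated data with known changes in 50 probe sets per size among 46352. For the response of the Yr5 isoline at 24 h, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 16%, 54%, 74% and 88% of cases, with 8 false calls. For the difference of responses at 24 h, they were recovered in 2%, 22%, 48% and 70% of cases, with 4 false calls. The simulated noise was drawn independently for each array, without the shared deviation of same-numbered arrays.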

Results

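Transcript levels were measured on 48 arrays from leaves of the Yr5 and yr5 isolines of wheat, inoculated with the stripe rust fungus or mock-inoculated and harvested after 6, 12, 24 or 48 h. Each of the 16 groups held 3 arrays, 1 per biological replication, and their number limits the precision. Array medians ran from 88.6 to 121.2 signal units. Of 46352 probe sets tested, 1090 carried a gene symbol, so most called probe sets have no name here. Values are means of log2(signal + 16), given with their SD; changes are inoculated minus mock on the log2 scale, given with the standard error and the adjusted p of limma.

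The responses to inoculation show which transcript levels differ between inoculated and mock leaves of each isoline. Whether a probe set without a gene symbol measures RNA of the plant or of the fungus was not tested. In the Yr5 isoline at 24 h, COMT1 (LOC543449), which encodes the caffeic acid O-methyltransferase of lignin synthesis, rose 5.01-fold. Its level was 12.50 ± 0.35 (n = 3) in inoculated and 10.18 ± 0.40 (n = 3) in mock leaves, a change of 2.33 ± 0.24 with adjusted p = 1.7e-07. LOC543287 rose from 5.75 ± 0.93 to 10.69 ± 0.50 (n = 3 each), a change of 4.94 ± 0.70 with adjusted p = 6.0e-05 (4.01 to 5.11 over the alternatives, lowest with an offset of 64). Its level in mock leaves lies under the array medians of 6.71 to 7.10 at 24 and 48 h in both isolines, so the size of its change depends on the offset. LOC542830 rose by 1.91 ± 0.31 (adjusted p = 5.7e-04) and LOC542838 by 1.77 ± 0.26 (adjusted p = 7.7e-05). In each of these genes all 3 inoculated arrays lay above all 3 mock arrays, which the rule for named genes requires of every gene it picks at 1 time. The call held in each without any 1 of the 6 arrays. LOC543313 rose by 3.36 ± 0.72 (adjusted p = 0.026) and LOC542826 by 2.73 ± 0.51 (adjusted p = 0.0038), again with all 3 inoculated arrays above all 3 mock arrays. The adjusted p of LOC543313 was 0.17 without inoculated replicate 1, 0.12 without inoculated replicate 2, 0.15 without mock replicate 1 and 0.14 without mock replicate 3. That of LOC542826 was 0.051 without mock replicate 2 and 0.091 without mock replicate 3. Over the alternatives each of these 2 genes passed in 9 of 10 settings. The highest adjusted p was 0.054 for LOC543313 and 0.20 for LOC542826.

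In all, 85 probe sets were called in the Yr5 isoline at 24 h, 80 higher and 5 lower in inoculated leaves, and 6 named genes were among them. All 85 had groups that did not overlap, which a call itself favours. Among all tested probe sets 12.0% did not overlap, where chance gives 10%. The count was 54 without inoculated replicate 1 and 55 without inoculated replicate 3. Leaving replicate number 2 out of every group gave 13, and leaving number 3 out gave 97. With the replicate number as a block within each time, it was 844 (461 higher, 383 lower). At an unadjusted p under 0.05 limma had 3041 probe sets, above the share of 0.05 that chance alone gives.

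In the yr5 isoline at 24 h, COMT1 rose 5.44-fold, from 10.18 ± 0.34 to 12.62 ± 0.21 (n = 3 each), a change of 2.44 ± 0.24 with adjusted p = 2.2e-08. LOC543287 rose from 6.47 ± 0.79 to 11.00 ± 0.57 (n = 3 each), a change of 4.54 ± 0.70 with adjusted p = 1.8e-04 (3.91 to 4.69 over the alternatives, lowest with an offset of 64). LOC542830 rose by 2.78 ± 0.31 (adjusted p = 3.1e-07) and LOC542838 by 1.59 ± 0.26 (adjusted p = 4.0e-04). These 4 genes had all 3 inoculated arrays above all 3 mock arrays and held their call without any 1 of the 6 arrays. LOC543313 rose by 3.86 ± 0.72 (adjusted p = 0.0031) and LOC543097 by 3.49 ± 0.66 (adjusted p = 0.0035), in 3 of 3 arrays; without mock replicate 1 their adjusted p was 0.054 and 0.085. LOC543252 was the named gene that fell, by 1.54 ± 0.32 (adjusted p = 0.011), with all 3 inoculated arrays below all 3 mock arrays. Its adjusted p was 0.077 without inoculated replicate 1, 0.075 without inoculated replicate 2 and 0.22 without mock replicate 1. Over the alternatives LOC543252 passed in 9 of 10 settings, with 0.29 as the highest adjusted p. A further 4 genes with LOC symbols rose by 1.24 to 2.21, and for each of them the call ended without 1 array for at least 3 of the 6 arrays.

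In all, 162 probe sets were called in the yr5 isoline at 24 h, 152 higher and 10 lower in inoculated leaves, with 11 named genes among them. Of these, 159 had groups that did not overlap, which a call itself favours. Among all tested probe sets 11.3% did not overlap, where chance gives 10%. The count was 99 without inoculated replicate 1, 103 without inoculated replicate 2 and 88 without mock replicate 1. Leaving replicate number 2 out of every group gave 32, and leaving number 3 out gave 289. With the replicate number as a block within each time it was 1237 (690 higher, 547 lower). At an unadjusted p under 0.05 there were 3249, above the share of 0.05 that chance alone gives.

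PR5, a thaumatin-like pathogenesis-related protein, had large differences that did not pass the test over all probe sets. At 24 h it was at 11.57 ± 0.67 in inoculated and 7.47 ± 1.76 in mock leaves of the Yr5 isoline (change 4.10 ± 1.28, adjusted p = 0.34, all 3 inoculated arrays above all 3 mock arrays). Its levels in the yr5 isoline were 11.53 ± 1.17 and 6.66 ± 3.15 (change 4.87 ± 1.28, adjusted p = 0.089, higher in 3 of 3 same-numbered pairs). At 48 h the change was 5.06 ± 1.28 in the Yr5 isoline (adjusted p = 0.23) and 4.05 ± 1.28 in the yr5 isoline (adjusted p = 0.85), each with all 3 inoculated arrays above all 3 mock arrays. With the replicate number as a block within each time the adjusted p at 24 h was 0.042 in the Yr5 isoline, with a range over the alternatives of 0.042 to 0.44, and 0.0086 in the yr5 isoline, with a range of 0.0086 to 0.48. At 48 h in the Yr5 isoline it was 0.028, with a range of 0.024 to 0.35.

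PEAMT1, a phosphoethanolamine methyltransferase of choline synthesis, and SAHH, the S-adenosylhomocysteine hydrolase that serves methyl transfer, passed the threshold at 24 h in both isolines under the block within each time and not in the fit without a block. The other settings were run on them for the Yr5 isoline alone, where PEAMT1 also passed under quantile normalization. PEAMT1 changed by −1.28 ± 0.33 (adjusted p = 0.12 without the block) in the Yr5 isoline and −0.95 ± 0.33 (adjusted p = 0.38) in the yr5 isoline, lower in 3 of 3 same-numbered pairs in each. SAHH changed by 1.20 ± 0.41 (adjusted p = 0.46) and 1.17 ± 0.41 (adjusted p = 0.41), higher in 3 of 3 pairs in each.

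**Figure D1:**
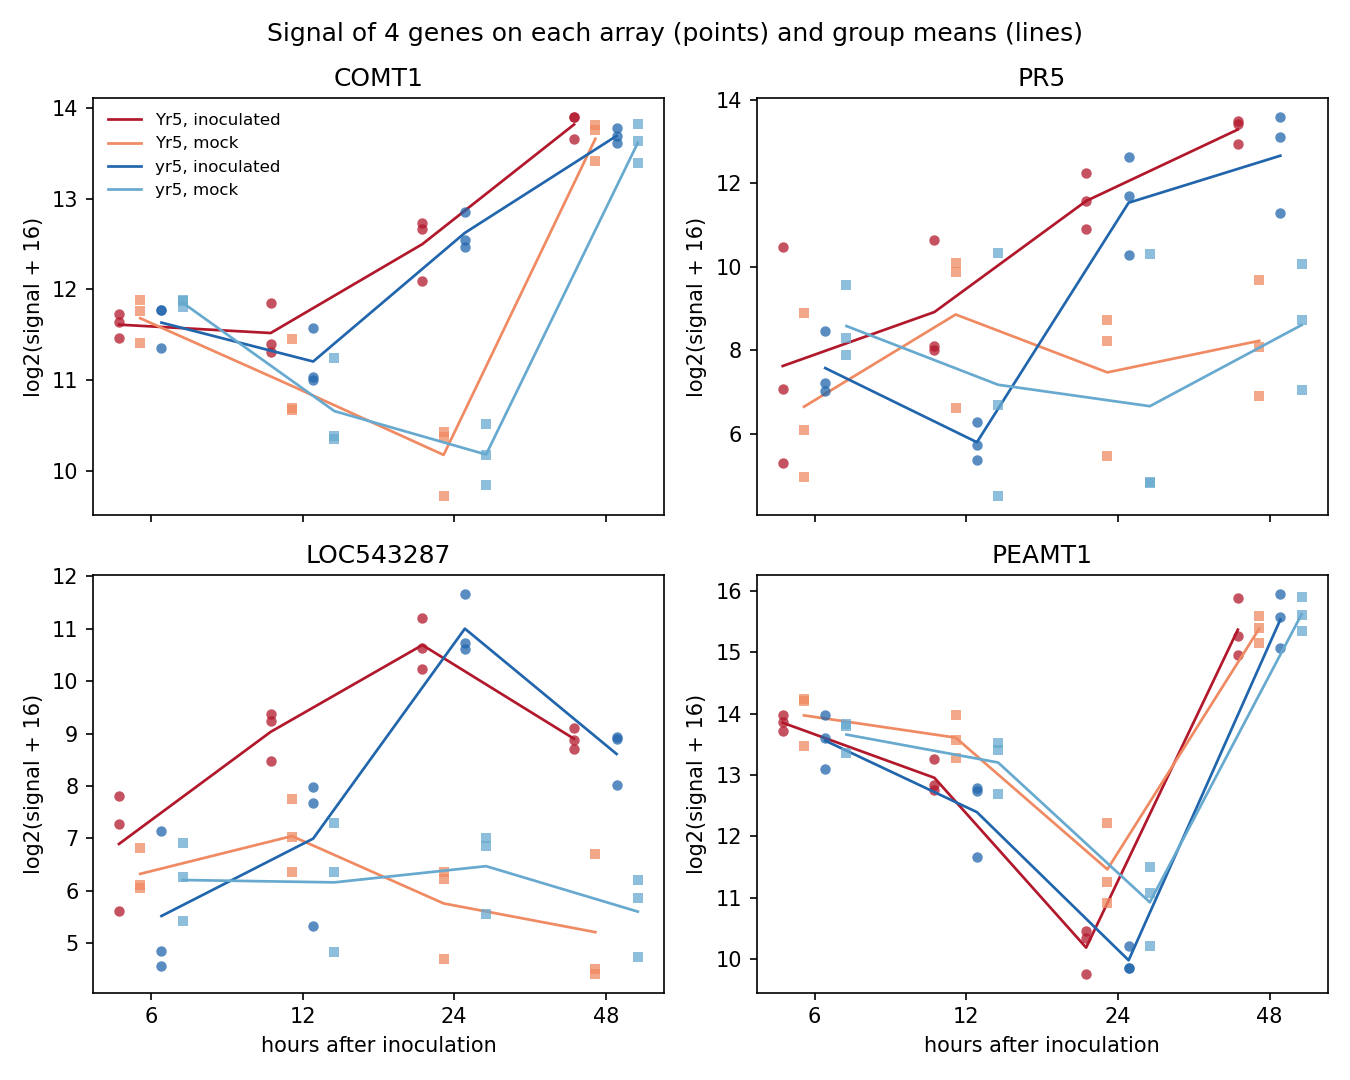
Level of COMT1, LOC543287, PR5 and PEAMT1 as log2(signal + 16) on the vertical axis against hours after inoculation, with a point per array (n = 3 per group) and lines through the means of the inoculated and mock groups of each isoline. At 24 h the inoculated means of COMT1 are 12.50 and 12.62, against 10.18 in the mock leaves of both isolines, while at 48 h all 4 group means lie between 13.62 and 13.82.

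At the other times few probe sets were called. In the Yr5 isoline at 48 h LOC543287 rose from 5.21 ± 1.29 to 8.90 ± 0.20 (change 3.69 ± 0.70, adjusted p = 0.018) and LOC543342 from 8.41 ± 0.63 to 11.88 ± 0.32 (change 3.48 ± 0.59, adjusted p = 0.0048), each with all 3 inoculated arrays above all 3 mock arrays. The change of LOC543287 over the alternatives ran from 2.54 with an offset of 64 to 3.69, and the adjusted p was 0.20 with only the compared arrays. Both calls ended without some single arrays, while the changes stayed. The change ran from 3.30 to 4.44 for LOC543287 and from 3.17 to 3.80 for LOC543342. The adjusted p of LOC543287 was 0.093 without inoculated replicate 1, 0.071 without 2 and 0.088 without 3, and 0.11 without mock replicate 2 and 0.24 without mock replicate 3. That of LOC543342 was 0.062 without inoculated replicate 1, 0.075 without mock replicate 1 and 0.061 without mock replicate 3. In the yr5 isoline at 48 h neither of these genes was called, though LOC543287 changed by 3.01 and LOC543342 by 2.82. The Yr5 response minus the yr5 response was 0.68 for LOC543287 (95% interval −1.31 to 2.67) and 0.65 for LOC543342 (−1.02 to 2.33). COMT1, by contrast, differed at 48 h by 0.16 ± 0.24 in the Yr5 isoline and 0.08 ± 0.24 in the yr5 isoline, at 12 h by 0.58 and 0.55, and at 6 h by −0.07 and −0.22, none past the test.

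The Yr5 isoline had 3 probe sets called at 6 h, 5 at 12 h and 17 at 48 h (16 higher, 1 lower); in the yr5 isoline 2, 5 and 4, all higher in inoculated leaves. All these called probe sets had groups that did not overlap, which a call itself favours. Among all tested probe sets 7.16% to 8.89% did not overlap at these times, where chance gives 10%. The limma counts at an unadjusted p under 0.05 were 1654, 1628 and 1503 in the Yr5 isoline and 1732, 1975 and 1761 in the yr5 isoline. Each lies under the share of 0.05 of tested probe sets that chance alone gives. With the block within each time the counts were 5, 21 and 110 in the Yr5 isoline and 3, 15 and 23 in the yr5 isoline.

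Single arrays moved these counts. At 6 h the count of the Yr5 isoline was 1 without inoculated replicate 2 and 0 without mock replicate 1. At 12 h it was 2, 1 and 0 without inoculated replicates 1, 2 and 3, and 1 without mock replicate 1, 2 or 3. At 48 h it was 6 and 7 without inoculated replicates 1 and 2, and 9 and 4 without mock replicates 1 and 3. At 6 h the yr5 isoline had 1 without inoculated replicate 2. At 12 h it was 3, 1 and 9 without inoculated replicates 1, 2 and 3, and 3 without mock replicate 3. At 48 h it was 2 without inoculated replicate 1, 10 without inoculated replicate 3 and 0 without mock replicate 1.

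The probe sets called at 24 h moved less at the other times. Those of the Yr5 isoline had a median change in the called direction of 0.31 at 6 h, 1.01 at 12 h, 2.68 at 24 h and 1.26 at 48 h. Those of the yr5 isoline had medians of 0.17, 0.59, 2.51 and 0.68. Since they were chosen at 24 h, their values at 24 h are favoured by the choice.

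The difference of responses asks whether the isolines respond differently to the fungus. The lines may differ in more than Yr5, so neither a difference nor its absence can be credited to that gene alone. For COMT1 at 24 h the Yr5 response minus the yr5 response was −0.12 (95% interval −0.79 to 0.56). For LOC543287 it was 0.40 (−1.59 to 2.39), for LOC542830 −0.87 (−1.76 to 0.01) and for PR5 −0.77 (−4.43 to 2.89). LOC543097, called in the yr5 isoline alone, differed by −1.13 (−3.02 to 0.76). These intervals are not adjusted over probe sets, and some others left out 0, such as that of raftin1a at −1.97 (−3.54 to −0.39). No difference passed the test: limma called 0 probe sets at each of the 4 times, with 1429, 1309, 1277 and 1192 at an unadjusted p under 0.05 at 6, 12, 24 and 48 h. At 6 h, 1 was called without inoculated replicate 2 of the Yr5 isoline, and likewise without inoculated replicate 1 or 3 of the yr5 isoline. At 48 h, 2 were called without inoculated replicate 3 of the Yr5 isoline, and 1 without its mock replicate 2 or without inoculated replicate 2 of the yr5 isoline. With the block within each time 6 were called at 48 h, none with a gene symbol. In simulated data, a difference of 2 on the log2 scale at 24 h was recovered in 22% of cases and one of 4 in 70%, so smaller differences were mostly not detectable with 3 arrays per group. The simulated noise was independent between arrays, so the shared deviation of same-numbered arrays was not part of it.

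The probe sets called at 24 h overlapped between the isolines, which do not share mock arrays. Of 85 and 162 called, 65 were called in both with the same sign, where independent lists would share 0.26 of the higher and 0.001 of the lower ones. The lists are not independent, however. Both isolines share the estimate of spread of each probe set, and some genes are counted by several probe sets. The values for independent lists may thus be too low, and the overlap was not tested against them. Over all tested probe sets the responses of the isolines at 24 h correlated by 0.295. The 85 called in the Yr5 isoline had the same sign in the yr5 isoline in 82 cases, and their median change was 2.68 in the first and 2.59 in the second. The 162 called in the yr5 isoline had the same sign in the Yr5 isoline in 156 cases, with medians of 2.51 and 1.94. At 48 h, 15 of 17 and 4 of 4 called probe sets had the same sign in the other isoline, and 2 were called in both.

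**Figure D2:**
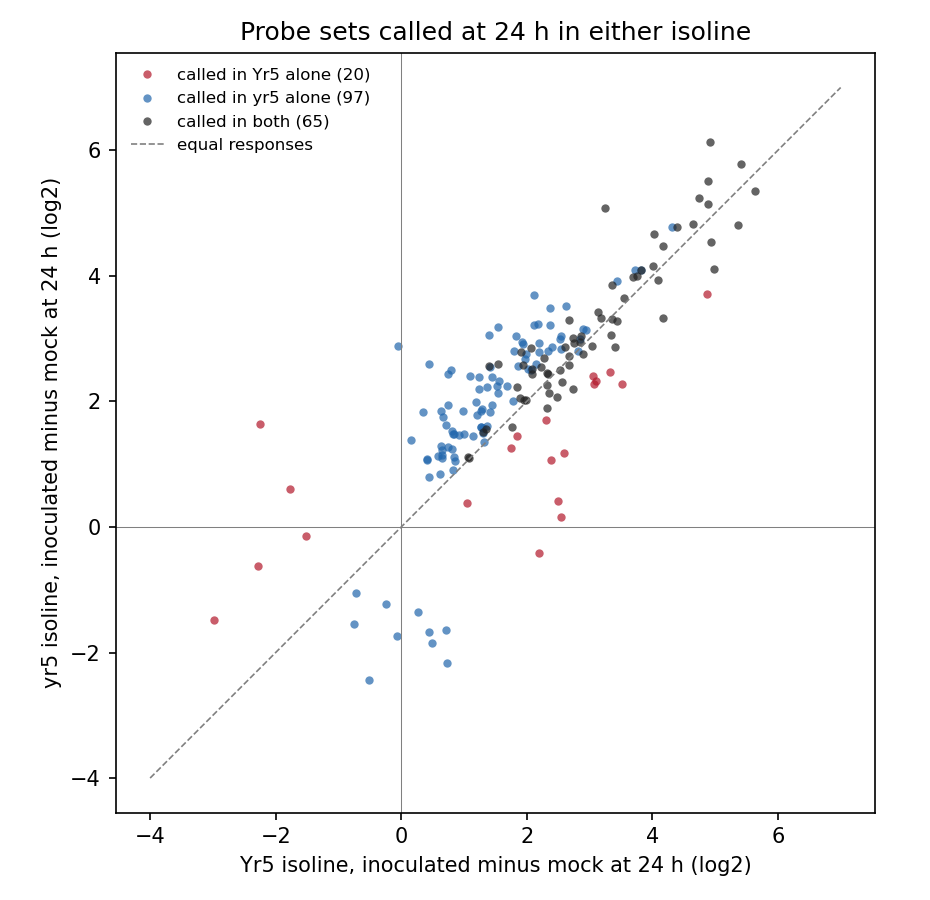
Change at 24 h (inoculated minus mock, log2) in the Yr5 isoline on the horizontal axis and in the yr5 isoline on the vertical axis, with a point for each probe set called in either isoline and a dashed line for equal responses. The 65 probe sets called in both, the 20 called in the Yr5 isoline alone and the 97 called in the yr5 isoline alone are shown, some of them far from the line; 82 of the 85 and 156 of the 162 have the same sign in the other isoline, and no difference between the isolines passed the test.

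Averaged over the 4 times, the Yr5 isoline responded with LOC543287, which rose by 2.80 ± 0.35 (2.16 to 2.80 over the alternatives, adjusted p = 2.8e-06, higher in 11 of 12 same-numbered pairs), and LOC542838, which rose by 0.93 ± 0.13 (adjusted p = 2.4e-05, 11 of 12 pairs). Both held their call without any 1 replicate number. LOC543313 rose by 2.15 ± 0.36 (adjusted p = 8.4e-04, 10 of 12 pairs), with adjusted p = 0.34 without replicate 1 and 0.053 without replicate 2. COMT1 rose by 0.75 ± 0.12 (adjusted p = 3.1e-04, 8 of 12 pairs), with adjusted p = 0.33 without replicate 1. The yr5 isoline responded with these 4 genes too. LOC543287 rose there by 1.92 ± 0.35 (1.59 to 1.97 over the alternatives, adjusted p = 0.0027, 9 of 12 pairs), with adjusted p = 0.84 without replicate 1 and 0.070 without replicate 2. LOC542838 rose by 0.77 ± 0.13 (adjusted p = 6.5e-04, 11 of 12 pairs), with adjusted p = 0.26 without replicate 1 and 0.053 without replicate 2. LOC543313 rose by 2.47 ± 0.36 (adjusted p = 9.4e-05, 12 of 12 pairs), with adjusted p = 0.17 without replicate 1. COMT1 rose by 0.71 ± 0.12 (adjusted p = 6.8e-04) in 6 of 12 pairs, with adjusted p = 0.23 without replicate 1 and 0.12 without replicate 2. The mean of COMT1 rests mostly on 24 h. Its changes at 6, 12, 24 and 48 h were −0.07, 0.58, 2.33 and 0.16 in the Yr5 isoline. In the yr5 isoline they were −0.22, 0.55, 2.44 and 0.08. LOC606348 changed by −1.47 (−1.53 to −0.91 over the alternatives, adjusted p = 0.0057, lower in 11 of 12 pairs), with adjusted p = 0.27 without replicate 1 and 0.14 without replicate 3.

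The mean response called 116 probe sets in the Yr5 isoline (114 higher, 2 lower) and 125 in the yr5 isoline (118 higher, 7 lower), with 2594 and 3397 at an unadjusted p under 0.05. Without replicate numbers 1 and 2 in turn the counts were 41 and 40 in the Yr5 isoline and 16 and 19 in the yr5 isoline; without number 3 the yr5 isoline had 296. With the block within each time they were 641 (427 higher, 214 lower) and 1303 (674 higher, 629 lower). The mean difference of responses over the 4 times, added after the data were seen, called 0 probe sets in limma. At an unadjusted p under 0.05 it had 1242, fewer than chance alone gives.

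In mock leaves the near-isogenic lines differ before any contact with the fungus, and this comparison gives the background. Per the growth protocol, each genotype had its own flats per replication, and rows of seedlings were assigned to harvest times. The 12 mock arrays of an isoline may therefore come from fewer independent plantings, while the fit takes them as independent. The adjusted p and the counts of same-numbered pairs may thus overstate the evidence. LOC780602 was higher in the Yr5 isoline by 2.11 ± 0.22 (adjusted p = 7.9e-09), at 8.65 ± 1.01 against 6.54 ± 0.58 (n = 12 each), in 12 of 12 same-numbered pairs. LOC542793 was lower in the Yr5 isoline, at 7.52 ± 0.95 against 8.65 ± 0.73 (n = 12 each), a difference of −1.13 ± 0.26 (adjusted p = 0.023) in 12 of 12 pairs, with adjusted p = 0.18 without replicate 1 and 1.0 without replicate 2. The probe sets furthest apart have no gene symbol. The furthest lower in the Yr5 isoline differed by −5.09, at 6.71 against 11.80 (adjusted p = 1.6e-26, 12 of 12 pairs), and the furthest higher by 4.64, at 10.18 against 5.55 (adjusted p = 3.1e-17, 12 of 12 pairs; 3.64 to 4.64 over the alternatives).

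In all, 221 probe sets differed between the isolines in mock leaves, 100 higher and 121 lower in the Yr5 isoline, and 155 of them by at least 2-fold. The count was 145 without replicate 1 and 123 without replicate 2, and 418 with the block within each time. In inoculated leaves, a contrast added after the data were seen, 220 differed, and 172 probe sets were called in both contrasts with the same direction. These counts too take arrays of different times as independent, so flats shared between times may make them too high.

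Time in mock leaves also changes leaf age and hour of day, and it sets the scale for the responses. Between 24 and 48 h the tubulin genes rose in mock leaves: tubb1 by 2.76 ± 0.23 (adjusted p = 6.2e-13), tubb3 by 2.58 ± 0.16 (adjusted p = 5.1e-16) and TUBA by 1.46 ± 0.11 (adjusted p = 6.8e-14), each higher in 6 of 6 same-numbered pairs. Of the 9 tested genes of the list of dividing cells, 6 rose, 1 (H2A-3) fell and 2 did not pass, with the same counts adjusted over the list alone. H2A-3, a histone, fell by 0.44 ± 0.16 (adjusted p = 0.034, 6 of 6 pairs), while its other probe set differed by 0.77 (adjusted p = 0.14). Outside the lists, the histone gene wcH2B-8 rose by 4.22 ± 0.53 (adjusted p = 2.2e-08) in 6 of 6 pairs. The gibberellin 20-oxidase gene GA20ox1d, which serves gibberellin synthesis, rose by 3.54 ± 0.36 (adjusted p = 1.1e-10) in 6 of 6 pairs. No called gene named for time in mock leaves turned its direction under quantile normalization or median centring.

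Several genes were lowest at 24 h and highest at 48 h in mock leaves. PEAMT1 fell by 2.62 ± 0.23 from 6 to 24 h (adjusted p = 6.5e-11) and rose by 4.31 ± 0.23 from 24 to 48 h (adjusted p = 4.7e-18). SAHH fell by 1.96 ± 0.29 (adjusted p = 3.1e-06) and rose by 4.05 ± 0.29 (adjusted p = 1.8e-14). COMT1 fell by 1.59 ± 0.17 (adjusted p = 3.1e-09) and rose by 3.46 ± 0.17 (adjusted p = 1.7e-19), each in 6 of 6 pairs for all these changes. The photosynthesis genes PRK, which encodes phosphoribulokinase, and PsbP, of photosystem II, also fell and then rose, though neither was shown to be highest at 48 h. PRK fell by 0.80 ± 0.27 (adjusted p = 0.038) and rose by 1.0 ± 0.27 (adjusted p = 0.0034). PsbP fell by 0.95 ± 0.23 (adjusted p = 0.0024) and rose by 0.96 ± 0.23 (adjusted p = 8.8e-04). These changes of PRK and PsbP were in 6 of 6 pairs. From 24 to 48 h the xylanase inhibitor gene XIP-I fell by 2.25 ± 0.32 (adjusted p = 2.5e-07) and the phytochelatin synthase gene PCS1 by 1.56 ± 0.19 (adjusted p = 1.5e-08). Glc1, of the list of PR proteins, fell by 1.72 ± 0.21 (adjusted p = 7.9e-09), while its dimmer probe set differed by 0.02; each of these falls was in 6 of 6 pairs.

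The F test over time in mock leaves called 18350 probe sets, 39.6% of those tested, and 12036 without replicate 2. Against 6 h, 1865 were called at 12 h (1077 higher, 788 lower), 7694 at 24 h (3988 higher, 3706 lower) and 12464 at 48 h (6788 higher, 5676 lower). The contrast of 48 with 24 h, added after the data were seen, called 15691 (8330 higher, 7361 lower). A fall from 6 to 24 h followed by a rise to 48 h was called in 2234 probe sets, and a rise followed by a fall in 2634. The first principal component, with 27.3% of the variance, set the 48 h arrays of both isolines and treatments (lowest score 131.9) apart from all other arrays (highest score −3.90).

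**Figure D3:**
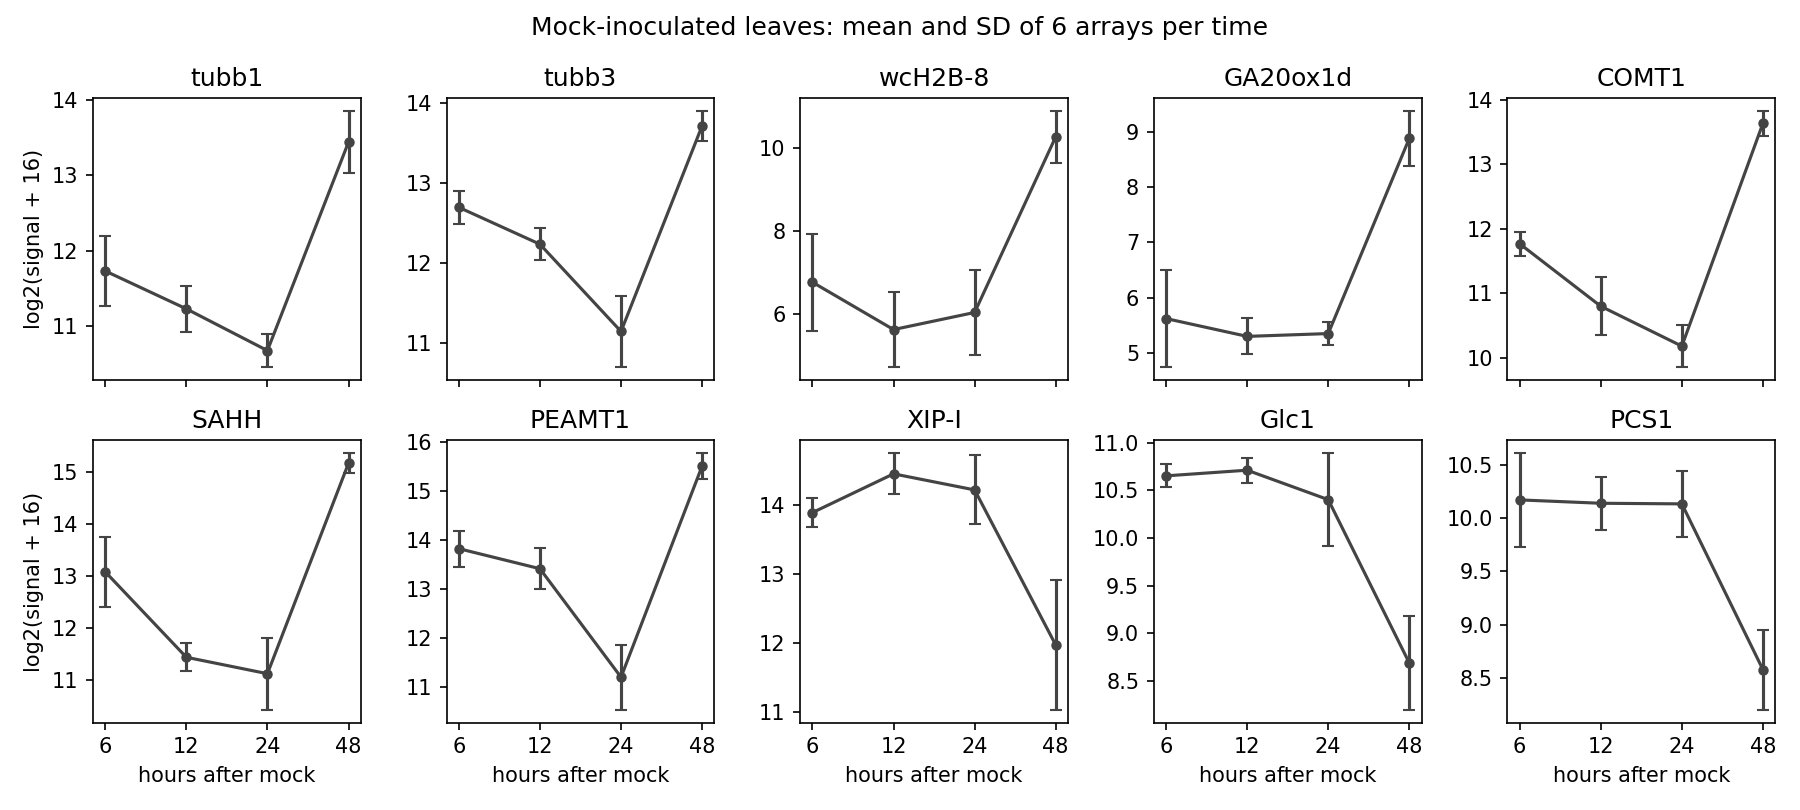
Level of 10 genes in mock leaves as log2(signal + 16) on the vertical axis against hours after mock inoculation; points are means of 6 arrays over both isolines and bars their SD. COMT1 goes from 11.77 at 6 h to 10.18 at 24 h and 13.64 at 48 h, and XIP-I from 14.22 at 24 h to 11.97 at 48 h.

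By list, the responses moved few genes. The phenylpropanoid and lignin list holds 1 tested gene, COMT1, which rose at 24 h in both isolines. A list of 1 gene leaves nothing to adjust over, so its p is unadjusted; at an unadjusted p under 0.05 COMT1 also differed at 12 h in both. Of 3 PR protein genes 0 passed in any response in limma, and adjusted over the list alone 1 (PR5) was higher at 24 and 48 h in both isolines. The salicylate list holds 1 gene (wci) and had 0 calls over all genes tested. At an unadjusted p under 0.05 alone, wci differed by 0.80 at 6 h and −0.59 at 48 h in the Yr5 isoline and by −0.78 at 6 h in the yr5 isoline, with a difference of responses of 1.58 at 6 h; none of these passed an adjusted test. Adjusted over the list alone, 1 of 2 cold, dehydration and LEA genes was higher at 12 h in the yr5 isoline (1.88). Likewise 1 of 9 genes of dividing cells was higher at 6 h in the yr5 isoline (1.54), with a difference between the isolines at 6 h (−1.58); both lists had 0 calls over all genes tested.

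For the other lists with tested genes, the responses and differences called 0 genes over all genes tested and 0 adjusted over the list alone: peroxidases (2 genes), glutathione and antioxidant (2), tryptophan and shikimate (1), photosynthesis (3), ribosome (2), sucrose with starch and fructan (3), leaf epidermis (2), vascular tissue (1), stomata (1) and housekeeping (1). The limma counts at an unadjusted p under 0.05 are those given with each comparison, over all probe sets. With the block within each time, PR5 was called as given above, and in the yr5 isoline at 24 h Prx1 of the peroxidase list (−0.99), the catalase gene CAT1 (−0.39), PsbP (−0.61) and the ribosomal protein gene RPL9 (−0.99) were called lower. A second probe set of the antioxidant gene GSTZ1 (0.61) and, outside the lists, raftin1a (2.01) were called higher there. In the mean responses the block called Prx1 lower in the Yr5 (−0.60) and yr5 isolines (−0.56), TSA of the tryptophan list lower (−0.28 and −0.25) and the same probe set of GSTZ1 higher (0.39 and 0.53). It called PR5 higher and RPL9 lower (−0.39, adjusted p = 0.0498) in the Yr5 isoline alone, and CAT1 lower (−0.19) and raftin1a higher (1.14) in the yr5 isoline alone. Without the block, the mean responses adjusted over the list alone had PR5 higher in the Yr5 isoline (2.55) and the yr5 isoline (1.64), and 1 antioxidant gene higher in the yr5 isoline (0.42). The set test of the list of dividing cells passed in 0 of 12 comparisons; its smallest adjusted p was 0.11, and 0.12 with an estimated correlation. The list of fungal sequences, like 9 others, had no tested gene.

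In mock leaves from 24 to 48 h, 2 of 3 photosynthesis genes and 2 of 3 sucrose, starch and fructan genes rose, as did 1 of 2 glutathione and antioxidant genes, COMT1, 1 of 2 epidermis genes, the vascular gene XTH and the housekeeping gene TEF1 (by 0.50 ± 0.18, adjusted p = 0.025, 6 of 6 pairs). Another probe set of TEF1 rose by 1.34 ± 0.19 (adjusted p = 1.6e-07). The salicylate gene wci fell by 0.72 ± 0.20 (adjusted p = 0.0043, 6 of 6 pairs), as did 1 of 3 PR protein genes. Counts adjusted over the list alone were the same, except that among PR proteins 1 was also higher. The lists of peroxidases, tryptophan, ribosome, cold and stomata had 0 calls both ways, with 1 probe set per gene. Another probe set of Prx1, of the peroxidase list, rose by 2.33 ± 0.49 (adjusted p = 1.9e-04). From 6 to 24 h, 3 of 9 genes of dividing cells fell and 1 rose (4 and 1 adjusted over the list alone), 2 of 3 photosynthesis genes fell, 1 antioxidant gene rose and 1 fell, and 1 epidermis gene and XTH fell.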

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

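The comparisons of the response at 24 h with the response at other times, the fit with a block within each time, the exchange of the isolines in 1 replicate number, and the tests of the replicate numbers and of the 48 h mock leaves were chosen only after the result was seen.

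The response to inoculation differed between times for 7 named genes, as the mean of both isolines tested by limma; the genes had been picked for their calls, mostly at 24 h, which favours this. For COMT1 the response at 24 h exceeded that at 6 h by 2.53 (adjusted p = 1.4e-08), at 12 h by 1.82 (adjusted p = 3.7e-05) and at 48 h by 2.27 (adjusted p = 3.3e-07). For LOC543287 it exceeded that at 6 h by 4.79 (adjusted p = 1.1e-04) and at 12 h by 3.32 (adjusted p = 0.044). For LOC542830 the excess was 2.30 over 6 h (adjusted p = 2.8e-05) and 1.97 over 12 h (adjusted p = 8.9e-04). LOC542838 exceeded 6 h by 1.35 (adjusted p = 0.0061), LOC542826 exceeded 6 h by 2.37 (adjusted p = 0.029), LOC543235 exceeded 6 h by 1.42 (adjusted p = 0.016), and LOC543342 exceeded 12 h by 2.87 (adjusted p = 0.034). Against 48 h only COMT1 passed without the block. The excess over 48 h was 1.38 for LOC543287 (adjusted p = 0.91), 1.17 for LOC542830 (0.25) and 0.83 for LOC542838 (0.47). It was 1.61 for LOC542826 (0.49), 0.30 for LOC543235 (0.98) and −0.74 for LOC543342 (0.97), whose response was larger at 48 h. With the block, LOC542830 (0.014), LOC542838 (0.013) and LOC542826 (0.012) passed against 48 h too. With the block within each time 4 more genes passed: LOC543313 against 6 h (adjusted p = 0.022) and 12 h (0.032), and against 48 h LOC543097 (0.014), LOC543252 (0.034) and LOC100125738 (0.0059). The level of COMT1 in mock leaves was itself lowest at 24 h, at 10.18, and 13.64 at 48 h, so its change there starts from different levels; the size of the response at equal starting level was not tested.

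The response differed between the isolines at 48 h in 6 probe sets under the block within each time (2 higher and 4 lower in the Yr5 isoline), none with a gene symbol. Without the block their adjusted p ran from 0.18 to 1.0, and 0 were called.

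Same-numbered arrays deviated together, and a block within each time raised the calls at 24 h from 85 to 844 and from 162 to 1237. A shared hybridisation or array batch is a candidate explanation: hybridisation spike-ins, which carry no plant RNA, were highest in replicate 3 in 15 of the 16 groups. RNA integrity that differs between replicate numbers, within a time or over all times, cannot be told apart from it: the mean 3' to 5' log2 ratio of plant controls differed between numbers by at most 0.27 over all times and 0.26 at 24 h, under the 0.5 set for it. It differed by 0.59 at 12 h, though, and the ubiquitin ratio deviated together in same-numbered inoculated and mock arrays (correlation 0.76 over 24 pairs). No label states what the replicate number marks, and plants grown or handled together, which were not tested, stay open beside the batch.

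The isolines differed in 221 probe sets in mock leaves, where differences between single harvests of mock plants are argued against, since 98.2% of these (217 of 221) kept their direction in the inoculated leaves. These leaves may share flats with the mock leaves. Single flats were therefore tested by exchanging the isolines in 1 replicate number, taken as a replication with its own flats. Each exchange called 0 probe sets, so the calls depended on the replicate numbers going the same way. This does not decide on flats, since these exchanges are too few for a share under 0.05 and no label states what the number marks. A sequence difference under the probes of single probe sets is argued against only weakly as the cause of the whole pattern. Of uncalled sibling probe sets 71.1% (64 of 90, exact 95% interval 60.6 to 80.2) went in the called direction, above the 50% written earlier as the bound. With called siblings included 78 of 104 did. The interval takes siblings as independent, though the 104 fall into 53 clusters, so it may be too narrow. Siblings that share sequence would also move together under a sequence difference. Such a difference stays open for many single probe sets, since these 104 moved by a median of 0.17 against 1.11 for the furthest changed probe set of each cluster (for the uncalled, 0.15 against 1.35 for all called ones). A difference in expression near Yr5 or elsewhere between the lines stays open too, untested.

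Mock leaves at 48 h stood apart from those at 24 h. Time of day is argued against as the whole cause, since 48 h against 24 h, which share a clock time, called 15691 probe sets and 24 h against 6 h 7694, and RNA integrity at 48 h is argued against too, with a largest mean change of the 3' to 5' log2 ratio of 0.12 (standard error 0.20). A batch shared by all arrays of 48 h, which no label names and the design confounds with time, cannot be told apart from a change in the leaves. Hybridisation spike-ins give it little support: they changed by −0.19 on average, and by −0.24, −0.37 and 0.03 in replicates 1, 2 and 3, while the called probe sets moved by medians of 1.14, 1.20 and 1.25 and 96.3% of them the same way in all 3; a value of 0.03 is too near 0 to count as the opposite direction set as the bound. Leaf age, which the design changes with time, stays open and was not tested.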

How the results depend on the processing

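The block within each time, leaving out a replicate number from every group for a response at 1 time, and the contrasts named in the processing as added were chosen only after the result was seen; the other alternatives were planned. No named gene past the threshold reversed its direction; the set test of dividing cells in the Yr5 isoline at 6 h turned from lower (adjusted p = 0.92) to higher (0.96) under the block within each time, passing in neither. Of 71 results past the threshold for probe sets picked by the rule for named genes (38 with a gene symbol), 39 (27 with a symbol) stayed past it under every planned setting that tested them, other than leaving out arrays. Among these, LOC606348 in the mean response of the yr5 isoline was not tested under the stricter filter. Leaving out arrays ended several of these calls as given in the report, and all 71 stayed past the threshold under both blocks.

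Counts are of called probe sets; the cause of each move was not tested, except that leaving out arrays leaves fewer of them. In the Yr5 isoline at 6, 12, 24 and 48 h the counts were 3, 5, 85 and 17, and in the yr5 isoline 2, 5, 162 and 4. With only the compared arrays, which leaves fewer residual degrees of freedom, the Yr5 isoline had 0 at 6 h and 56 at 24 h, and the yr5 isoline 0 at 6, 12 and 48 h and 54 at 24 h. With an offset of 64, the Yr5 isoline had 12 at 12 h and 35 at 48 h, and the yr5 isoline 2 at 48 h. Quantile normalization gave 2 in the Yr5 isoline at 12 h and 2 in the yr5 isoline at 48 h, where median centring gave 1. Without the filter the yr5 isoline had 2 at 48 h, and the difference of responses at 12 h called 1. The stricter filter gave 8 in the Yr5 isoline at 12 h. Without the variance trend, the Yr5 isoline had 1 and the yr5 isoline 3 at 12 h, and the difference of responses at 24 h called 1. Array weights gave 8 at 12 h and 67 at 48 h in the Yr5 isoline, 9 at 48 h in the yr5 isoline, and 183 and 193 for the mean responses of the Yr5 and yr5 isolines (116 and 125 otherwise).

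With the replicate number as a replicate block over all arrays, the Yr5 isoline had 10 at 12 h, 138 at 24 h and 36 at 48 h, the yr5 isoline 271 at 24 h, and its mean response 194. With the block within each time, the Yr5 isoline had 5, 21, 844 and 110 at the 4 times, the yr5 isoline 15 at 12 h, 1237 at 24 h and 23 at 48 h, the difference of responses at 48 h 6, the mean responses 641 and 1303, and the isolines in mock leaves 418. The blocks changed no other count by over 1.5 times, and 36 results of picked probe sets (32 with a symbol) not past the threshold passed it under the block within each time. For time in mock leaves this block is aliased with time unless its terms are set to sum to 0 within a time, so its count there, 21661, is not used; the responses compared between times are not aliased.

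Leaving out arrays gave these ranges: in the Yr5 isoline 0 to 4 at 6 h, 0 to 2 at 12 h, 13 to 97 at 24 h and 0 to 20 at 48 h; in the yr5 isoline 0 to 3, 1 to 10, 32 to 289 and 0 to 13. Differences of responses called 0 to 1 at 6 h, 0 at 12 and 24 h and 0 to 2 at 48 h. The mean responses ranged from 40 to 108 and from 16 to 296, the isolines in mock leaves from 123 to 181, time in mock leaves from 12036 to 17198, and the set tests stayed at 0.

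Splitting the 6 arrays of a response otherwise gives 10 splits, too few for a share under 0.05. As many calls came from 1 split (the real one) in the Yr5 isoline at 6, 12 and 24 h, with 1, 1 and 2 as the highest other, and in the yr5 isoline at 6 and 12 h, with 0 and 1. From 2 splits they came in the Yr5 isoline at 48 h (17, highest other 170) and the yr5 isoline at 24 h (162, highest other 338), and from 5 in the yr5 isoline at 48 h (4, highest other 51). The 170, 338 and 51 come from splits that set both arrays of replicate 2 against both of replicate 3. The 170 and 51 are several times the real count and point to a structure of the samples; the values with the block within each time are 110, 1237 and 23. The other splits that part every same-numbered pair called at most 1 in every response. For the differences of responses, 100 of 100 drawn splits called as many as the real 0, which holds for any split and so decides nothing; the highest, 182, 180, 612 and 1966, point to a structure of the samples. For the mean responses, the isolines in mock leaves and time in mock leaves, 1 of 100 splits (the real one) called as many, with 10, 9, 16 and 5395 as the highest other. A random grouping is therefore unlikely to give these counts, which says nothing of single calls. For the isolines the splits were drawn within each time, so arrays that may share flats between times were not kept together.

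Array median centring moved the median of all probe sets of the difference of responses at 12 h from −0.03 to 0.13 and that of the response of the yr5 isoline at 12 h from 0.02 to −0.08; other medians moved by under 0.1. Signal over background limits dim probe sets, of which 14827 were not tested.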

Other observations

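The probe sets described here were singled out only after the result was seen.

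Among probe sets without a gene symbol, 1 was higher in inoculated leaves at every time in both isolines, by 4.05 to 6.13, with all 3 inoculated arrays above all 3 mock arrays in 8 of 8 responses, 7 of which limma called. It exceeded its array's median on 24 of 24 inoculated and 8 of 24 mock arrays. Another was higher by 1.82 to 5.07 in the same 8 responses, 6 of them called, and exceeded the array median on 24 of 24 inoculated and 2 of 24 mock arrays. Mean mock levels of 6.25 and 5.98 lie under the array medians of 6.71 to 7.10, so these sizes depend on the log offset; with an offset of 64 and the other alternatives, the mean response of the yr5 isoline ran from 4.94 to 5.71 for the first and from 3.49 to 4.51 for the second. Chance gives groups that do not overlap in 10% of single responses, but these probe sets were picked for their calls, which favours such groups. The list of fungal sequences had no tested member, so whether these probe sets measure RNA of the plant or of the fungus was not tested.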
